A study of Mus musculus with 8 samples.

How the data were processed

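RNA from mouse proB colonies was measured on 8 Affymetrix expression arrays, 4 from wild-type and 4 from HMGN1-overexpressing transgenic cells. Per the labels' protocols, bone marrow was plated in a B cell methylcellulose medium, in which early B cell progenitors grow as colonies, and the colonies were harvested at 1 week. The arrays were summarised with RMA (background correction, quantile normalization and probe summary), per the submitters' processing notes. The deposited values were an intensity on a linear scale, between 5.80 and 17578 over all arrays, with 1 value per gene and array. The scale was read from the values themselves, since log2 values had been planned for, and log2 of the intensity was taken before any test. No value lay below 1. RMA brings the arrays to a common distribution, so a change in total RNA would not show, and fold changes of dim genes are understated where background remains in the signal.

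The 27835 rows carry Ensembl mouse gene IDs with no symbol, and the version of the gene definition is not given in the sources used here. A reference table of 49997 genes held 0 Ensembl IDs, so 0 of the IDs could be paired with a symbol. The files do not pair them either. The overexpressed gene, the Polycomb target list and the other lists, 35 lists with 660 symbols fixed before the data were examined, were therefore not tested, nor was the 3' to 5' ratio of control probes. Gene IDs are printed for at most 2 genes that rose and 2 that fell.

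Groups came from the sample labels. Nothing says whether the 4 arrays of a genotype came from separate mice, so p-values measure the spread between these samples, which may be technical in part. No 2 arrays were copies of each other: exactly equal values were found for 0.0144% to 0.108% of genes in each pair. There were 0 columns of other samples.

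Differences between genotypes were fitted over all 8 arrays with limma (lmFit and eBayes, version 3.58.1, R 4.3.3) on log2 intensity, with no filter and no replicate block. P-values were adjusted by the Benjamini-Hochberg method over 27835 genes with a threshold of 0.05, and fold changes are HMGN1-overexpressing over wild-type. Errors are SD over n = 4 arrays or the standard error (SE) of the fit. Single values per array were compared by a two-sided exact permutation test, for which the smallest possible p with 4 against 4 arrays is 0.0286. The fixed rule for named genes took those past the threshold with groups that did not overlap and a mean log2 value of at least 6 in the higher group, up to the number of IDs allowed.

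Lists of G1, S and G2M phase genes by Ensembl ID were added after the data had been opened and before the lists were tested. They were derived from published phase-marker pairs of mouse embryonic stem cells: a gene was kept when it was the higher member in at least 0.9 of at least 10 pairs of its phase and in less than 0.5 of the pairs of other phases. They held 93, 63 and 80 genes, of which 92, 62 and 79 were measured. Lists were tested with limma's camera (preset correlation 0.01, and an estimated correlation) and fry, adjusted over the lists.

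The fit was tested on simulated data with the means and spreads of the real arrays, in which 200 of 27835 genes were changed. Noise was drawn independently for each gene and array. Variation shared between genes was thus not simulated, and the shares recovered need not hold for the real arrays. Of 50 genes changed by 1.5-fold, 70% were called, against 90% at 2-fold, 100% at 3-fold and 96% at 4-fold. Of the unchanged genes, 6 were called. Alternatives were array medians subtracted, quantile normalization, a replicate block, genes above the median signal only, a trended and robust variance, array weights, log2(intensity + 16) and each array left out. Using the mean of the probe sets of a gene, or all probe sets, would change nothing with 1 row per gene and was not run.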

Results

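Gene expression was measured in proB cell colonies grown from mouse bone marrow, in 4 wild-type samples and 4 samples of a transgenic line that overexpresses HMGN1, a nucleosome-binding protein encoded in the chromosome 21q22 region named in the study's title. Each array gave an intensity for 27835 genes. Array medians ranged from 95.8 to 100.1, a range that the normalization itself keeps narrow. The number of arrays limits the precision: the median residual SD of a gene was 0.12 on the log2 scale and the median 95% interval of its fold change was ± 0.18.

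The comparison asks which transcripts differ when HMGN1 is overexpressed. Most differences were small, and how many genes passed depended on the fit. By limma with Benjamini-Hochberg adjustment, 4 genes passed the threshold, 3 higher and 1 lower in HMGN1-overexpressing colonies. ENSMUSG00000094231 rose 1.91-fold, from an intensity of 97.9 ± 10.2 to 187 ± 17.7 (SD, n = 4 each; log2 fold change 0.93, SE 0.094, limma adjusted p = 0.0251). ENSMUSG00000097567 rose 1.68-fold, from 107 ± 5.81 to 180 ± 14.6 (log2 fold change 0.75, SE 0.074, limma adjusted p = 0.0251). The third rose by 0.58 on the log2 scale, from 82.2 ± 6.29 to 123 ± 1.62 (limma adjusted p = 0.0413). ENSMUSG00000024065 was the 1 gene that fell, 2.38-fold, from 540 ± 58.6 to 229 ± 38.0 (log2 fold change -1.25, SE 0.129, limma adjusted p = 0.0251). In each of the 4, every array of one genotype lay above every array of the other. With the first residual component as a covariate, chosen after the data were seen, limma called 241 genes (105 higher, 136 lower), the 4 among them. That component came from the residuals of these same data and held 34.5% of their variance. Removing it lowers the residual spread, and the adjusted p does not allow for its choice. With the replicate number as a block, 0 genes were called. The 4 calls sit near the threshold: leaving out 1 array gave between 0 and 40 called genes, and only 2 of the 4 stayed called without wild-type replicate 1. No gene was called without wild-type replicate 2 or 3 or without HMGN1 replicate 2, 3 or 4, 1 gene was called without wild-type replicate 4, and 40 without HMGN1 replicate 1, among them all 4, while the genes at an unadjusted p under 0.05 numbered 2266 to 3038.

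Below that threshold, 2902 genes had an unadjusted p under 0.05, of which 1623 were higher and 1279 lower, against 1392 by chance. Genes of high signal leaned upward: among the 6959 genes of highest signal 673 were higher and 224 lower, while among the 6959 of lowest signal 188 were higher and 258 lower, a direction that turned without wild-type replicate 4 (229 higher, 217 lower). Without wild-type replicate 3, which stood apart from the other arrays, the genes of highest signal gave 564 higher and 409 lower. The 2 genotypes did not overlap for 1896 genes, 6.81% of all against the 2.86% that chance gives, with 1155 higher and 741 lower. Among the other splits of the arrays into 4 and 4, the highest count of such genes was 1842. It came from wild-type replicates 2 and 3 with HMGN1 replicates 1 and 4 against the rest, a split unrelated to genotype. The next highest was 1158. For 27487 genes (98.7%) the 95% interval of the difference lay inside 2-fold in both directions.

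**Figure D1:**
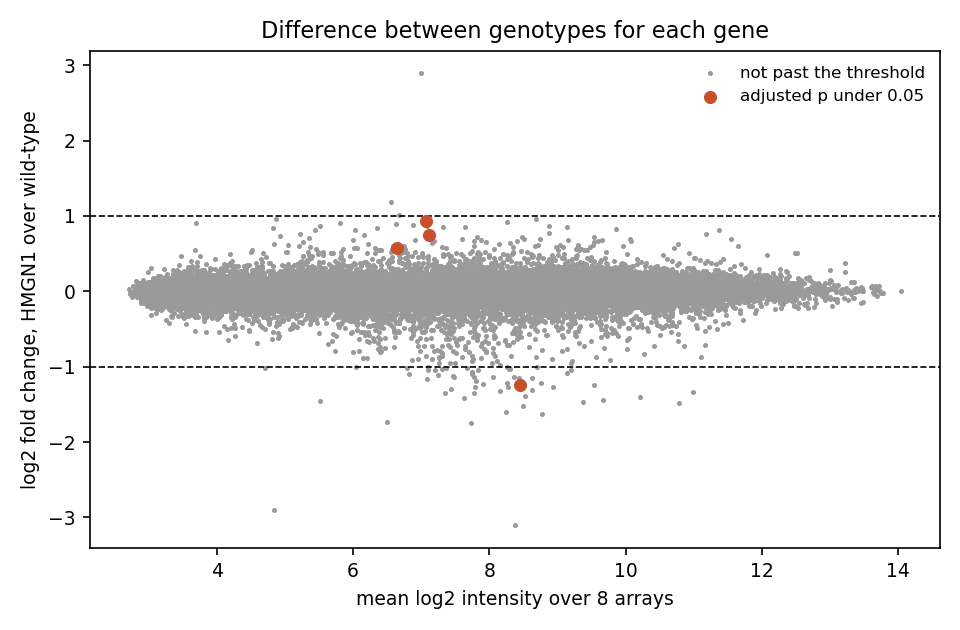
Log2 fold change (HMGN1-overexpressing over wild-type) against mean log2 intensity over 8 arrays, 1 point per gene; dashed lines mark 2-fold and large points the 4 genes past the threshold. Of the 60 genes beyond the lines, 57 lie below.

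Large differences ran downward. A mean difference of 2-fold or more was found for 60 genes, 3 higher and 57 lower, and 1 of the 60, ENSMUSG00000024065, was past the threshold. With the first residual component as a covariate, 18 of the 57 lower genes passed by limma. The 57 genes had a median log2 fold change of -1.19. Their mean, relative to each gene's mean over all arrays, was 0.52 to 0.79 in the wild-type arrays, -0.04 in HMGN1 replicate 1 and -0.76, -1.01 and -0.75 in replicates 2, 3 and 4. Without HMGN1 replicate 1, 87 genes were lower by 2-fold, and without HMGN1 replicate 3, 38.

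The largest fall by mean, ENSMUSG00000036322, was chosen after its values were seen and rested on 3 of the 4 wild-type arrays. Its log2 value was 10.85 ± 0.18 (SD, n = 3) in wild-type replicates 2, 3 and 4 and 6.88 ± 0.15 (SD, n = 5) in the other arrays, among them wild-type replicate 1 at 7.13, which was close to the HMGN1-overexpressing arrays though above each of them. The log2 fold change was -3.10 (SE 0.738) and did not pass the threshold (limma adjusted p = 0.199). Without wild-type replicate 1 it was -4.03 and passed (limma adjusted p = 4.9e-07), but gene and array were both picked for the pattern, so that p is no evidence of a difference. Another gene had the opposite pattern, at 4.66 ± 0.19 in the same 3 arrays and 8.39 ± 0.16 in the other 5.

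**Figure D2:**
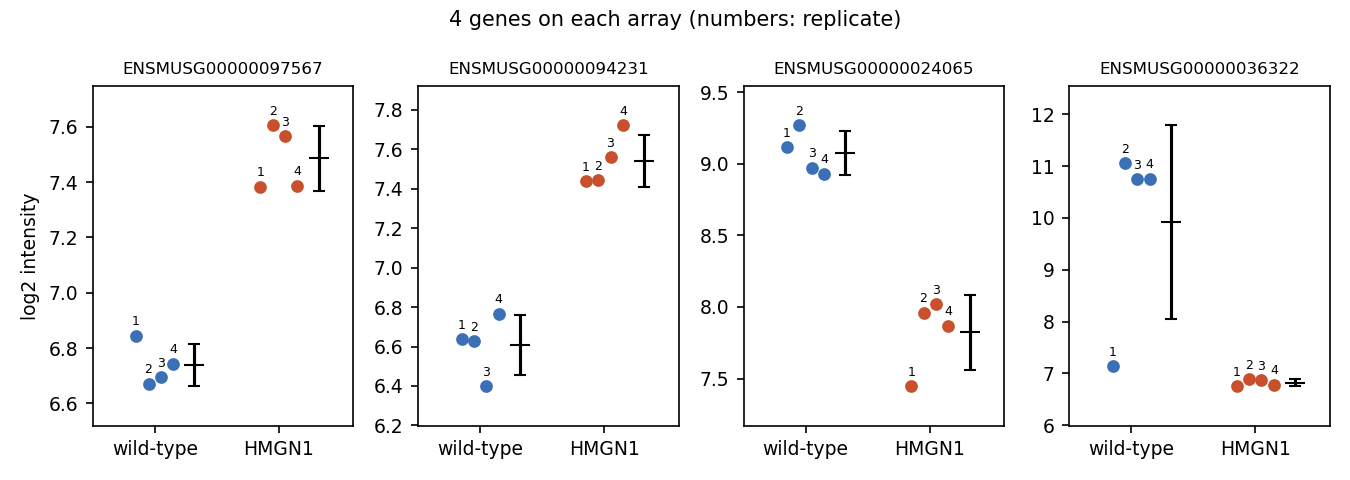
Log2 intensity of 4 genes on each array (points, numbered by replicate), with the mean and SD of each genotype as bars; y scales differ. In the rightmost panel wild-type replicate 1, at 7.13, lies just above the HMGN1-overexpressing arrays.

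Cell-cycle genes had slightly higher values in HMGN1-overexpressing colonies, though no single one passed over all genes. The mean log2 fold change was 0.10 for the G2M list, 0.09 for the S list and 0.06 for the G1 list. Adjusted over the list alone, 3 G2M genes passed and 0 of the others. Camera with its preset correlation placed all 3 lists above other genes (limma adjusted p = 8.9e-08, 1.7e-06 and 0.00051). None passed with an estimated correlation (limma adjusted p = 0.292 for each) or by fry for a shared direction (fry adjusted p = 0.158, 0.158 and 0.181). By fry for changes in either direction, the G1 list passed (fry adjusted p = 0.0148). The G2M and S lists did not (fry adjusted p = 0.0873 for each). The estimated correlations were 0.33, 0.17 and 0.18, far above the preset 0.01, so the p-values with the preset are likely too small. Exact permutation p over the arrays was 0.0571, 0.0286 and 0.114, with wild-type replicate 3 lowest in each list at -0.19, -0.15 and -0.14. Without that array the mean log2 fold changes were 0.06, 0.06 and 0.02. The last no longer passed the threshold by camera with the preset correlation (limma adjusted p = 0.0641). HMGN1 replicate 1, at 0.0006 in the G2M list, lay below wild-type replicate 2, at 0.0131. In the S list it was lowest of its genotype, at 0.0128, but above every wild-type array. Whether the list shifts are separate from that of the 57 lower genes was not tested.

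**Figure D3:**
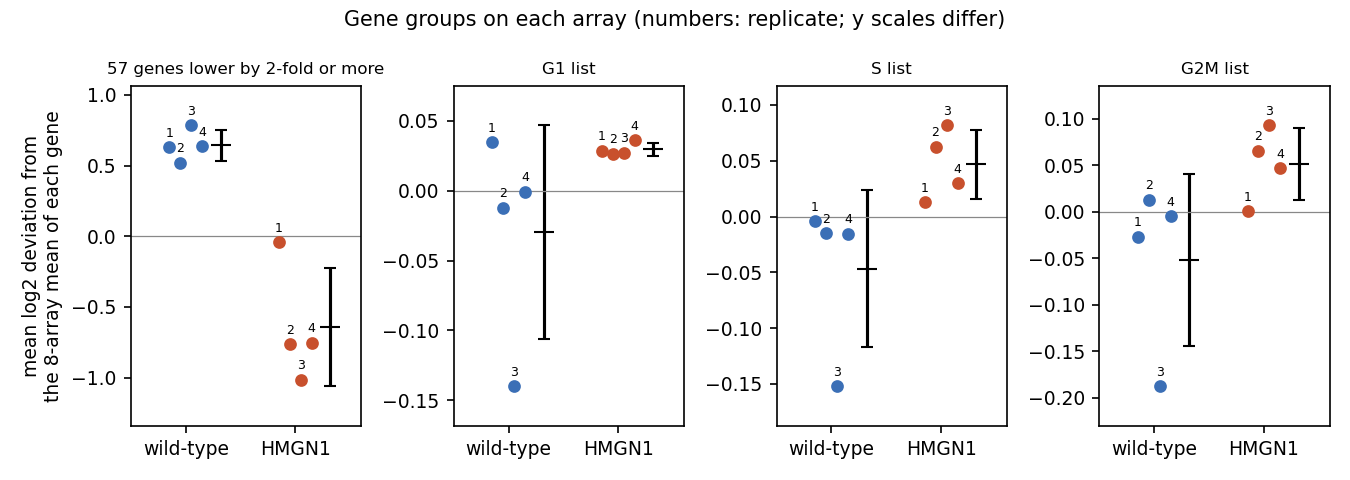
Mean log2 deviation of 4 gene groups on each array from each gene's mean over 8 arrays (points, numbered by replicate), with the mean and SD of each genotype as bars; y scales differ. Wild-type replicate 3 is lowest in the 3 cell-cycle lists, and HMGN1 replicate 1, at -0.04, is highest of its genotype for the 57 genes.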

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

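In this part the test of the cell-cycle lists on wild-type replicate 3 and the test against lists matched on signal were set before their results were seen; the tests for noise and for a wrong label were chosen afterwards. Wild-type replicate 3 lay far from the other wild-type arrays on the first principal component (29.9% of variance), at 36.2, and in the mean of the S list, at -0.152. HMGN1 replicate 4 lay apart from its group on the second component (21.4%), at -19.8. Of 26 groups of values examined, 3 had such an array, where chance gives about 1.3.

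Noise private to wild-type replicate 3 stays open: its deviations correlated with those of HMGN1 replicate 3 across genes above the median signal (r = -0.352, the largest in size of 4), but wild-type replicates 1 and 2 reached 0.298 and 0.268, so the test does not tell this array from others. A wrong label is argued against by its position of -0.127 on an axis built from the other arrays, with their group means at -0.5 (wild-type) and 0.5 (HMGN1): the other wild-type arrays, placed likewise, lay at -0.130 to -0.099, HMGN1 replicates 2 to 4 at 0.251 to 0.346, and HMGN1 replicate 1 at the midpoint (0.016). The G2M list lay below the other 7 arrays (-5.01 of their SD) and at percentile 0 of 10000 random lists matched on signal, so a lower signal of bright genes in general does not account for it. A different cell-cycle composition of this sample may be involved; but the G1 list was low too (-8.54 of their SD), so the values do not show a move from one phase to another, and fewer cycling cells or slower growth stay open.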

How the results depend on the processing

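The fit with the first residual component was added after the data were seen. The 4 called genes (3 higher, 1 lower) became 3 with array medians subtracted and with quantile normalization, 4 with a trended and robust variance or log2(intensity + 16), and 5 above the median signal or with array weights. With the first residual component as a covariate, 241 were called (105 higher, 136 lower), the 4 among them; the cause was not tested. Each other split, with its own component, called at most 1 (1 of 35 as large). Leaving out 1 array gave 0 to 40 called, 0 to 16 higher and 0 to 24 lower. The log2 fold changes of the 4 genes kept their sign, with limma adjusted p from 0.0178 to 0.24 over the alternatives. The balance of called genes did turn, with 16 higher and 24 lower without HMGN1 replicate 1 and 105 higher and 136 lower with the covariate. With the replicate number as a block, 0 genes were called (0 higher, 0 lower) by limma, with 2374 at an unadjusted p under 0.05. Arrays of the same number did not deviate together (r = -0.078, -0.088, -0.237 and -0.095), so the values gave no sign of pairing by number. The labels do not say whether samples were paired, so the fit with the block cannot be set aside. A floor at 1 was not run, as no value lay below it, nor were alternatives for symbol lists and the overexpressed gene. No signal over background was used here, so the detection of dim genes is unknown.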

Other observations

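The tests of called genes over splits, of wild-type replicate 1 and of late gene IDs were chosen after the results were seen. Those of the 57 lower genes, the low-signal genes and the cell-cycle lists by genotype were added once the data had been opened. They preceded their own results, but the excess of falls was itself a pattern seen in these data. Of the 35 splits of the arrays into 4 and 4, only the real one (1 of 35) called 4 genes, the highest other calling 2, and only the real one (1 of 35) gave 2902 genes at an unadjusted p under 0.05. A share of 1 in 35 is the smallest these splits allow, and the tests were chosen after the results, so it does not exclude chance. Leaving out 1 array gave 0 to 40 called genes and 2266 to 3038 at an unadjusted p under 0.05. The highest other split, 2702, parted wild-type replicates 2 and 3 with HMGN1 replicates 1 and 4 from the rest, and called 0 genes at an adjusted p under 0.05. It was picked as the highest, and whether the samples have a structure besides genotype was not tested.

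The excess of 57 falls over 3 rises was larger than in any other split (1 of 35, excess 54 against at most 38). The excess was picked from these same data and 1 of 35 is the smallest share possible, so chance is not excluded. No single array carried the excess: with 1 array left out, at least 38 genes were lower by 2-fold, and at least 30 of the 57 were. Within a genotype the 57 genes moved together: 69.8% of their variance, pooled over both genotypes, lay on 1 component, percentile 100 of random lists with a median of 37.2%. In a test added later, the share without HMGN1 replicate 1 was 68.4% against 48.5%. The HMGN1 arrays alone gave 78.2% against 49.0%. The margin was smaller in the wild-type arrays alone, at 72.3% against 62.6% (percentile 99). A candidate explanation is a smaller share of a minority cell population in the HMGN1-overexpressing colonies, and HMGN1 replicate 1 would hold more of it. Regulation shared by these genes in 1 cell type would give the same values and stays open, as does a biological difference by genotype. No cell type was assigned, because the IDs were not paired with gene names here, and what the genes are was not examined.

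Wild-type replicate 1 lay close to the HMGN1-overexpressing arrays in 2 genes with opposite directions, those with the widest gap. A wrong label is argued against by its position of -0.130 on the axis between genotypes (group means at -0.5 and 0.5), where the other wild-type arrays lay at -0.127 to -0.099. A gap of 2-fold or more between wild-type replicates 2 to 4 and the other 5 arrays was found for 3 genes, and 2 of the 56 splits into 3 and 5 gave as many, the highest 4; this split was picked because it showed the pattern, so that share does not exclude chance. An inherited difference between donors could give such levels. If donors differed along with genotype, other differences between the genotypes could come from it too, which was not tested. For these 2 genes the gap was at least 8.06 times the range within a level, and for the third gene 1.22 times; they were picked for their gap, so the test decides nothing and the explanation stays open.

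The study's title names loss of a repressive histone mark, and genes near background could rise if it were lost. This could not be decided: the median log2 fold change of the 6959 genes of lowest signal minus that of the rest was -0.0093, but the normalization gives every array nearly the same distribution, which holds this value near 0. Whether HMGN1 overexpression changes the cell-cycle composition was left open, with an adjusted p of 0.292 by camera with an estimated correlation, although the G2M list lay at percentile 100 of lists matched on signal, against higher values of bright genes in general. Genes with late Ensembl ID numbers did not differ beyond chance, as 22 of 35 splits gave a difference as large, and they had the higher median in 3 of 4 equal classes of signal.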
